A study of Mus musculus with 16 samples.

How the data were processed

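The 16 libraries were made from mouse SMARTA CD4 T cells sorted by flow cytometry on day 5, with 4 libraries in each of 4 groups: Tfh and Th1 cells from draining lymph nodes of protein-immunized recipients, and Tfh and Th1 cells from spleens of recipients infected with LCMV. The markers used in the sort are not given in the sources used here. Per the labels' protocols, RNA was purified on NucleoSpin columns, 1.5 to 2.0 ug of total RNA went into each library, and libraries were made with a SMARTER mRNA kit. Per the submitters' processing notes, reads were aligned with STAR to mm10, and the STAR version is not given in the sources used here. Per the file headers, featureCounts 2.0.0 counted fragments per gene of a refGene annotation, with both ends mapped, not chimeric, on the reverse strand and wholly within exons, so that multi-mapping reads were not counted and genes with near-identical copies are uncertain. The deposited values are raw fragment counts, not normalized and not pooled over replicates.

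The table holds 25239 genes, of which 16828 had at least 1 read, and 0 per-sample columns were left unused. Library totals ran from 5008269 to 7626869 counts, so that 1 fragment was 0.131 to 0.200 CPM of all counts. Rn45s, a ribosomal RNA precursor, took 17.9% to 28.0% of the counts and stayed in the totals, and an alternative left it out. Between replicates of a group, chi-square per degree of freedom of the counts was 3.64 to 10.4, above sampling noise, so no library repeats another, and each counts as 1 replicate, although the labels do not say that they came from separate animals. Mitochondrially encoded genes and the constant genes of immunoglobulins and T cell receptors were not analysed here.

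Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the default expression filter, which left 10857 genes, and the quasi-likelihood F test, two-sided, with all 16 libraries in 1 fit without a replicate block. Benjamini-Hochberg adjusted p-values under 0.05 within a comparison were called. The 5 comparisons were Tfh against Th1 after infection, Tfh against Th1 after immunization, immunization against infection in Tfh, immunization against infection in Th1, and the interaction, which is the Tfh-Th1 difference after immunization minus that after infection. CPM use the TMM-scaled library total, except that summed marker levels use the plain total. The SE of a log2 fold change is its size divided by the square root of F. Where a group had no reads for a gene, the fold is a bound against a floor of 3 fragments over the group, and with 1 to 3 fragments the ratio is given with its 95% counting interval.

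Before the data were examined, 23 gene lists were fixed: the Tfh, Th1 and cytotoxic, Th2, Th17 and regulatory T cell programs, interferon-stimulated genes, cell cycle, glycolysis, nuclear genes of oxidative phosphorylation, cholesterol synthesis, naive and memory precursor genes, coinhibitory receptors, early T cell receptor response genes, dissociation and heat shock genes, adhesion and migration receptors, cytokines and their receptors, T helper transcription regulators, and markers of B cells, myeloid and dendritic cells, CD8 T and NK cells, stromal cells, erythroid cells, and mitochondrially encoded genes. The last pair of lists, erythroid cells and mitochondrially encoded genes, could not be tested, which left 21. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 105 list comparisons, and again with an estimated correlation. The genes the text names were also set by a rule fixed in advance: 9 label checks in the Tfh-Th1 comparisons, the 6 highest and 6 lowest log2 fold changes per comparison among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries (no such condition for the interaction), leaving out predicted and unnamed genes and receptor segments, and the 3 members with the smallest adjusted p of each list described. Of the genes this rule names, 4 are not reported here, although counts and list results include them. Members named outside this rule are marked as named after their values were seen.

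The steps were tested on simulated negative binomial counts over 10857 genes, with the real dispersions and library sizes. Each gene had a single mean, that over all 16 libraries. Per comparison 67, 67 and 66 genes were changed by log2 0.5, 1 and 2 in a single group. The real comparisons called 1746 to 7142 genes, so the shares below do not carry over to them directly. Changes of log2 2 were recovered in 89.4% of cases for Tfh against Th1 after infection, 95.5% after immunization, 86.4% for the stimuli within Tfh, 93.9% within Th1 and 93.9% for the interaction. For log2 1 the shares were 71.6%, 67.2%, 76.1%, 79.1% and 61.2%, and for log2 0.5 they were 32.8%, 25.4%, 43.3%, 37.3% and 17.9%. False calls made up 5.15%, 6.02%, 4.86%, 4.11% and 4.17% of the calls in the same order, and 0 of 40 unchanged lists were called in each comparison. Genes were drawn independently, so these lists held no correlation between genes and could not test the preset correlation. Alternatives were RLE and upper-quartile factors, no filter, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, a robust fit, fits of the compared groups alone, replicate blocks, thinning to the smallest total, a minimum log2 fold change of 1, the fry test, and each library left out in turn. Alternatives chosen after seeing the data left out Rn45s, left out genes that share the B cell marker ratio, left out 2 immunization Tfh libraries, or added offsets for GC content and length, from a loess fit with span 0.5 on a GENCODE annotation of the reference, which gave values for 10682 of the tested genes (98.39%). Lists of granulocyte granule genes and Y-linked genes were also chosen after seeing the data.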

Results

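RNA was sequenced from SMARTA CD4 T cells, which carry a transgenic receptor for a peptide of the lymphocytic choriomeningitis virus (LCMV) glycoprotein. CD45.2+ SMARTA cells had been transferred into CD45.1 mice that were then either immunized with protein or infected with LCMV. On day 5, follicular helper cells (Tfh), which help B cells in germinal centres, and Th1 cells, which the labels also call non-Tfh cells, were sorted from the draining lymph nodes of immunized mice and from the spleens of infected mice. The 16 libraries form 4 groups of 4: immunization Tfh, immunization Th1, infection Tfh and infection Th1. Because every immunization library came from lymph node and every infection library from spleen, stimulus and organ changed together and are not separable in any comparison between them. Total counts ran from 5008269 to 7626869 fragments per library, and 10857 genes had enough reads to be tested. The labels do not say that same-group libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

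The first component of the log2 CPM values held 55% of the variance and ordered the libraries from the immunization groups through infection Tfh to infection Th1. The second component, with 18.7%, set Tfh apart from Th1 within each stimulus.

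**Figure D1:**
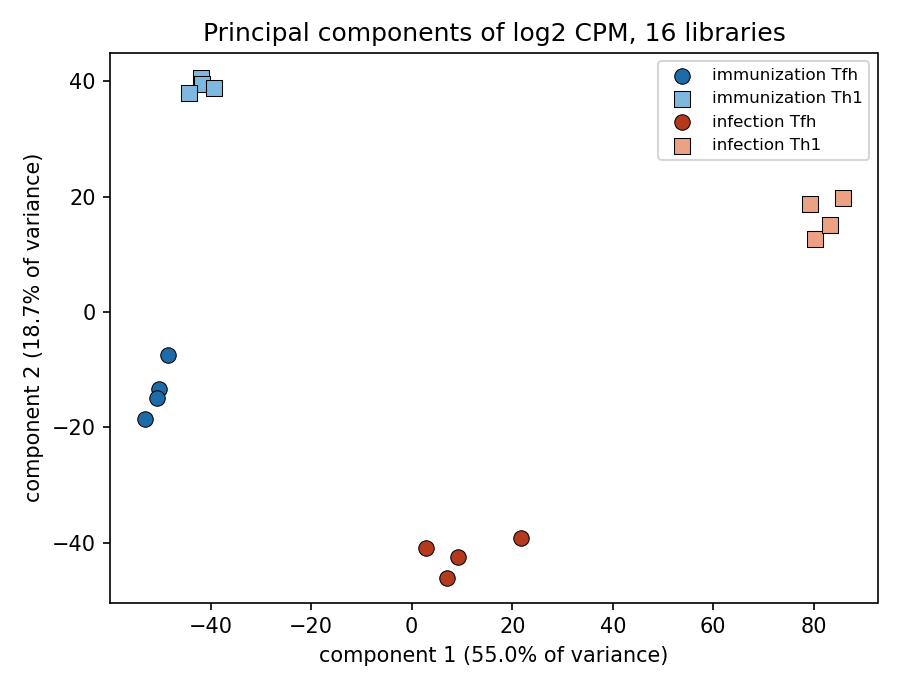
Principal components of log2 CPM for the 16 libraries, component 1 (55% of variance) on the x axis and component 2 (18.7%) on the y axis, 1 point per library. The 4 libraries of each group lie together, and the infection Th1 libraries lie farthest from the immunization libraries on component 1.

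The first comparison asked how Tfh and Th1 cells of infected mice differ. Cxcr5, the receptor that guides cells to B cell follicles, averaged 684 ± 25.9 CPM (SD, n = 4 for every group mean) in infection Tfh and 8.72 ± 1.54 CPM in infection Th1, a log2 fold change of 6.28 ± 0.17 (SE, adjusted p = 3.71e-16). Bcl6, the lineage-defining repressor of Tfh cells, stood at 60.9 ± 6.81 against 4.42 ± 2.22 CPM, while Gzmb, which encodes the cytotoxic protease granzyme B, stood at 29.8 ± 4.10 in Tfh against 1632 ± 131 CPM in Th1. In the deposited mm10 annotation Cxcr5 spans chromosome 9 from 44511787 to 44526444, Bcl6 chromosome 16 from 23965050 to 23988852 and Gzmb chromosome 14 from 56258836 to 56262334. The values count fragments that lie wholly within the exons of a gene.

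The other label checks after infection were as follows. Pdcd1, the inhibitory receptor PD-1, and Il21, a cytokine that acts on B cells, were higher in Tfh by 0.95 ± 0.08 and 1.46 ± 0.19 on the log2 scale (adjusted p = 1.30e-08 and 2.13e-06). Il4 was also higher in Tfh, by 3.80 ± 0.55 (adjusted p = 1.09e-05), at 2.74 CPM in Tfh and 0.184 CPM in Th1. Tbx21, the Th1 master regulator T-bet, had a log2 fold change of -1.86 ± 0.12, Ifng, the interferon-gamma gene, one of -1.60 ± 0.22 and Prdm1, which encodes the Bcl6 antagonist Blimp-1, one of -4.08 ± 0.28 (adjusted p = 2.60e-10, 6.03e-06 and 4.41e-10). For the chemokine receptor Cxcr3 the groups did not differ detectably, at 760 ± 76.4 and 729 ± 28.9 CPM (log2 fold change 0.06 ± 0.13, adjusted p = 0.730).

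In all, 2814 genes were higher and 2677 lower in Tfh than in Th1 after infection, of which 1986 changed at least 2-fold. Among the measured members of the Tfh program, 27 of 29 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.66e-19; adjusted p = 0.00529 with an estimated correlation). Tcf7 and Id3, transcription regulators, rose by 4.58 ± 0.09 and 5.38 ± 0.11 on the log2 scale, and P2rx7, an ATP receptor, by 5.74 ± 0.12. The members that fell, named after their values were seen, were Maf and Cd40lg (log2 fold changes -0.59 and -0.26). Of the 38 measured genes of the Th1 and cytotoxic program, 34 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 2.15e-16; adjusted p = 0.0186 with an estimated correlation). Besides Gzmb, the homing receptor Cxcr6 fell by 4.58 and the chemokine Ccl4 fell by 6.57 on the log2 scale, and the members that rose were Stat4 and Tnf, named after their values were seen.

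All 42 measured cell cycle genes were lower in Tfh, also adjusted over the list alone. Mki67, the proliferation marker, averaged 73.7 ± 30.0 CPM in Tfh and 310 ± 35.2 CPM in Th1, and Pcna and Cdt1, which act in DNA replication, had log2 fold changes of -1.42 and -1.67. The list had a median of -1.66 and a camera adjusted p of 1.31e-16, and an adjusted p = 0.276 with an estimated correlation. Glycolysis genes rose in 12 of 20 cases and fell in 4, also adjusted over the list alone, with Aldoc, Gpi1 and Tpi1 up by 4.31, 0.65 and 0.78 (camera adjusted p = 0.00669; adjusted p = 0.339 with an estimated correlation). The members that fell, named after their values were seen, were the glucose transporter gene Slc2a3 and the enzyme genes Hk2, Eno1 and Ldha, and with upper-quartile factors 15 rose and 2 fell. Nuclear genes of oxidative phosphorylation fell in 21 of 41 cases and rose in 2, or 24 and 2 adjusted over the list alone, with Cox7a2, Cycs and Cox5a at -0.72, -0.77 and -0.65 (camera adjusted p = 0.00305; adjusted p = 0.509 with an estimated correlation). These counts depend on the scaling: with upper-quartile factors 14 fell and 4 rose, and the median went from -0.22 to -0.13. Sdha was among the members that rose. Of 20 naive and memory precursor genes, 11 rose and 2 fell, or 12 and 2 adjusted over the list alone, among them Tcf7, Id3 and Slamf6 (camera adjusted p = 0.000376; adjusted p = 0.169 with an estimated correlation). The members that fell were Klf2 and S1pr1, which act in T cell egress from lymphoid organs. These members of both lists were also named after their values were seen. Of 62 transcription regulators of T helper cells, 34 rose and 18 fell, or 34 and 19 adjusted over the list alone, with Tcf7, Id3 and Tox2 leading (camera adjusted p = 0.0167; adjusted p = 0.143 with an estimated correlation).

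The largest changes by the fixed rule included genes with few or no reads in a group. Ica1l had 0 fragments over the 4 infection Th1 libraries and 6.06 CPM in infection Tfh, at least 44.4-fold higher against a floor of 3 fragments over the group. Intervals and floors cover counting error only. Ascl2, a regulator that promotes Tfh migration, had 1 fragment in infection Th1, a ratio of 290 with a 95% counting interval from 51.8 to 11500. Plagl1 also had 1 fragment, with a ratio of 168 (29.8 to 6660), and Wnt10a had 3, with a ratio of 155 (52.9 to 756). Sostdc1, a secreted BMP antagonist, and Padi4, an arginine deiminase, were higher in Tfh by 7.55 ± 0.29 and 6.41 ± 0.28 on the log2 scale. On the Th1 side, Ccl3 and Ccl4, inflammatory chemokines, averaged 69.3 and 147 CPM against 0.601 and 1.49 CPM in Tfh, and Havcr2, the inhibitory receptor TIM-3, averaged 92.2 against 1.44 CPM. F2rl2 had a log2 fold change of -5.93 ± 0.37, and Tmem37, with 3 fragments in Tfh, a ratio of 88.1 (29.8 to 431) in favour of Th1.

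B cell markers moved with the Tfh libraries: 16 of 18 were higher in infection Tfh, also adjusted over the list alone (camera adjusted p = 8.11e-09; adjusted p = 0.0245 with an estimated correlation). Cd22, Cd79a and Ms4a1 averaged 54.8, 35.6 and 17.4 CPM in infection Tfh against 6.64, 3.23 and 1.79 CPM in infection Th1, and the summed level of the 18 markers was 699 ± 65.6 against 179 ± 40.9 CPM of all counts.

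**Figure D2:**
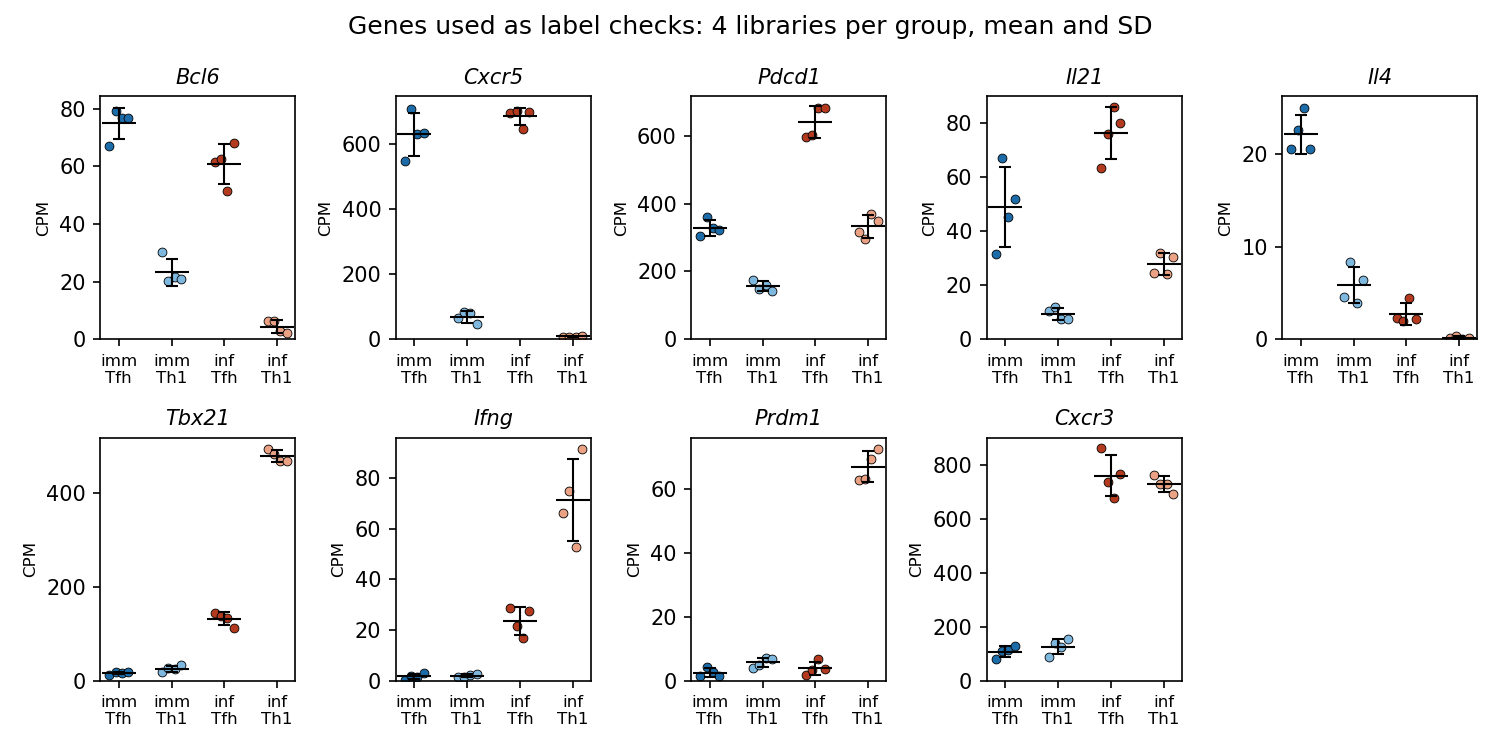
CPM (y axis) of the 9 genes used as label checks in each group (x axis; imm, immunization; inf, infection), 1 point per library, with the group mean and SD as bars. Cxcr5 and Bcl6 are higher in Tfh than in Th1 after both stimuli, and Tbx21, Ifng and Prdm1 reach 478, 71.4 and 67.1 CPM in infection Th1.

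The second comparison asked the same question after immunization, where both populations came from draining lymph nodes. Cxcr5 was again higher in Tfh, at 630 ± 65.9 against 68.4 ± 17.2 CPM, by 3.20 ± 0.14 on the log2 scale (adjusted p = 1.43e-12), and Bcl6 stood at 75 ± 5.35 against 23.2 ± 4.67 CPM (1.70 ± 0.17, adjusted p = 4.31e-07). Pdcd1, Il21 and Il4 were higher in Tfh by 1.07 ± 0.08, 2.37 ± 0.21 and 1.91 ± 0.25. Tbx21 averaged 16.4 CPM in Tfh and 25.1 in Th1 (log2 fold change -0.63 ± 0.15, adjusted p = 0.00515), and Ifng averaged 1.62 and 1.89 CPM, a difference not detectable at this depth (-0.24 ± 0.43, adjusted p = 0.774). Prdm1 had a log2 fold change of -1.27 ± 0.34 (adjusted p = 0.0134), and this call was lost without immunization Tfh replicate 4 (-1.08, adjusted p = 0.0562). Cxcr3 averaged 107 and 126 CPM (-0.24 ± 0.14, adjusted p = 0.281), and was called without immunization Th1 replicate 1 (-0.38, adjusted p = 0.0428).

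Of the genes tested, 833 were higher and 913 lower in immunization Tfh, and 609 of these changed at least 2-fold. The Tfh program rose in 16 of 29 genes and fell in 5, or 18 and 6 adjusted over the list alone (camera adjusted p = 1.84e-09; adjusted p = 0.0245 with an estimated correlation), led by Cxcr5, P2rx7 (1.81 ± 0.09) and Sostdc1 (4.28 ± 0.23). The members that fell, named after their values were seen, were Cd200, Il6ra, Batf, Izumo1r and Id3. Genes of the Th1 program fell in 19 of 38 cases and rose in 2, with the same counts adjusted over the list alone (camera adjusted p = 1.44e-07; adjusted p = 0.0787 with an estimated correlation). Gzmb, Nkg7, a granule membrane protein, and Selplg, a selectin ligand, had log2 fold changes of -2.13, -1.63 and -0.77. The members that rose, Cx3cr1 and Zeb2, were named after their values were seen. Cx3cr1 was near the floor, and its libraries overlapped, at 0.393 to 2.98 CPM in Tfh and 0 to 0.4 CPM in Th1. With the member that had no reads in a group set at its bound, the median of this list went from -0.59 to -0.70.

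Of 49 interferon-stimulated genes, 16 rose in Tfh and none fell, or 19 and none adjusted over the list alone, among them Ly6a, Isg15 and Stat2 by 0.59, 0.84 and 0.62 (camera adjusted p = 2.78e-05; adjusted p = 0.375 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 24 cases, or 12 adjusted over the list alone, including Cyp51, Fdps and Srebf2 by 0.93, 0.77 and 0.44 (camera adjusted p = 2.12e-06; adjusted p = 0.0992 with an estimated correlation). Naive and memory precursor genes fell in 11 of 20 cases and rose in 1, or 13 and 1 adjusted over the list alone (camera adjusted p = 2.15e-05; adjusted p = 0.103 with an estimated correlation). Within this list Dapl1 averaged 30.1 CPM in Tfh and 99.6 CPM in Th1, Ccr7, the receptor for lymph node homing, 412 and 933 CPM, and Satb1, a chromatin organizer, 135 and 247 CPM. The member that rose, named after its value was seen, was Cd27.

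B cell markers again moved with Tfh, and all 18 rose, also adjusted over the list alone (camera adjusted p = 9.78e-42; adjusted p = 0.000135 with an estimated correlation). Cd74, the invariant chain of class II antigen presentation, averaged 1735 ± 226 CPM in Tfh and 40.1 ± 6.64 CPM in Th1, and H2-Ab1 558 against 12.2 CPM. The summed level of the markers was 4909 ± 515 CPM in Tfh and 108 ± 20 CPM in Th1. Myeloid and dendritic markers rose in 12 of 19 cases, also adjusted over the list alone (camera adjusted p = 2.43e-07, and adjusted p = 0.0306 with an estimated correlation). Spi1, Tyrobp and Lyz2 stood at 17.1, 3.08 and 20.1 CPM in Tfh against 0.706, 0.482 and 6.26 CPM in Th1. The list median was 1.95, or 1.91 with the members without reads at their bound. Whether the reads of this list and of the B cell markers had separate sources was not tested.

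Several of the largest increases were likewise B cell genes: Ms4a1, which encodes CD20, averaged 141 against 1.10 CPM, Fcer2a, which encodes CD23, 99.2 against 0.753 CPM, and Ebf1, a B lineage regulator, had 3 fragments in Th1 and a ratio of 135 (46.0 to 658). Rasgrp3 had no reads in immunization Th1 and was at least 164-fold higher in Tfh, and Bcar3 and Dennd5b had 1 fragment each in Th1, with ratios of 668 (120 to 26400) and 205 (36.5 to 8150). The largest decreases in Tfh included Ifitm1, an interferon-induced membrane protein, Crocc, Hrh4, a histamine receptor, Pde8a and Ccr2, an inflammatory chemokine receptor, with log2 fold changes of -3.67, -3.21, -3.04, -2.68 and -2.65. The count of 1746 genes fell to 898 without immunization Tfh replicates 2 and 4, which held the most reads of Y-linked genes, and to between 877 and 1532 with any 2 libraries of that group left out.

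Between the 2 Tfh-Th1 comparisons, which share no libraries, 421 genes were higher in Tfh in both and 403 lower in both, against 216 and 225 for independent lists of these sizes. A further 307 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had r = 0.324 and rho = 0.262.

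The third comparison set immunization against infection within Tfh. S100a4, a calcium-binding protein, averaged 81.4 ± 16.2 CPM after immunization and 805 ± 56.2 after infection, S100a6 113 and 575 CPM, and Nkg7 13.2 and 226 CPM. Dapl1 was higher, at 30.1 CPM after immunization and 1.11 CPM after infection, as was Il7r, the interleukin-7 receptor, at 56.0 and 5.47 CPM. In total 2584 genes were higher and 2586 lower after immunization, 1492 of them at least 2-fold.

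The Th1 program fell in 26 of 38 genes and rose in 4, or 26 and 5 adjusted over the list alone (camera adjusted p = 7.16e-10; adjusted p = 0.0488 with an estimated correlation). The members that rose, named after their values were seen, were Il2ra, Cxcr6, Ly6c1 and Fasl. Naive and memory precursor genes rose in 13 of 20 cases and fell in 2, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.00559; adjusted p = 0.279 with an estimated correlation), and the members that fell, named after their values were seen, were Bcl2 and Cd27. Glycolysis genes fell in 17 of 20 cases, also adjusted over the list alone, including Tpi1, Aldoa and Pgk1 with log2 fold changes of -2.37, -1.48 and -1.59 (camera adjusted p = 8.32e-13; adjusted p = 0.0245 with an estimated correlation). Cell cycle genes fell in 37 of 42 cases, or 38 adjusted over the list alone, with Mcm6, Top2a and Cenpa at -0.93, -1.34 and -1.01 (camera adjusted p = 3.19e-08, and adjusted p = 0.496 with an estimated correlation). Infection Tfh replicate 3 was the highest of its group for Mcm6, Top2a and Cenpa, with Top2a at 359 CPM against 171 to 190 CPM in the others. Nuclear genes of oxidative phosphorylation fell in 39 of 41 cases, also adjusted over the list alone, including Sdhb and Ndufb9 at -0.75 and -0.83 (camera adjusted p = 2.37e-16; adjusted p = 0.0787 with an estimated correlation). With offsets for GC content and gene length, chosen after seeing the data, 25 of these 41 fell, the list median went from -0.60 to -0.27, and Sdhb and Ndufb9 went to -0.37 and -0.29. Interferon-stimulated genes fell in 23 of 49 cases and rose in 10, or 25 and 10 adjusted over the list alone, with Oas1a, Usp18 and Oas3 at -2.35, -2.18 and -1.38. The camera adjusted p for these was 0.0204, and 0.586 with an estimated correlation, 0.0520 without immunization Tfh replicate 3 and 0.0691 without infection Tfh replicate 1.

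The largest increases after immunization in Tfh were Nrn1, Ccr10, a chemokine receptor, St8sia6, a sialyltransferase, Il17rb, an interleukin-25 receptor chain, Lifr and Vdr, the vitamin D receptor, with log2 fold changes of 6.43, 6.22, 6.11, 5.67, 5.62 and 5.45. The largest decreases included genes of neutrophil granules and cytosol. Chil3, S100a9 and Ngp had no reads in immunization Tfh and were at least 83.1-fold, 83.1-fold and 57.2-fold lower there, with 8.21, 8.15 and 5.56 CPM in infection Tfh. S100a8 had 2 fragments, a ratio of 119 (32.6 to 993), and Mt3, a metallothionein, 1 fragment, a ratio of 228 (40.5 to 9060). Il1rl1, which encodes the interleukin-33 receptor, averaged 0.443 CPM after immunization and 48.1 CPM after infection.

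Myeloid and dendritic markers fell in 14 of 19 cases and rose in 2, also adjusted over the list alone, with Cd68 at 3.11 and 26.2 CPM beside S100a8 and S100a9 (camera adjusted p = 0.000108; adjusted p = 0.0787 with an estimated correlation). The members that rose, Flt3 and Spi1, were named after their values were seen. B cell markers rose in 17 of 18 cases, also adjusted over the list alone, with Ms4a1, Cd74 and H2-Ab1 up by 3.01, 2.70 and 2.70 (camera adjusted p = 3.96e-11; adjusted p = 0.0183 with an estimated correlation). The summed level of 17 granulocyte granule genes, a list chosen after seeing the data, was 0.565 ± 0.507 CPM in immunization Tfh and 46.4 ± 7.91 CPM in infection Tfh. Reads of 4 Y-linked genes, also chosen after seeing the data, summed to 0, 31.1, 3.81 and 30.5 CPM in immunization Tfh replicates 1 to 4 and to at most 2.63 CPM in any library of the other groups.

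**Figure D3:**
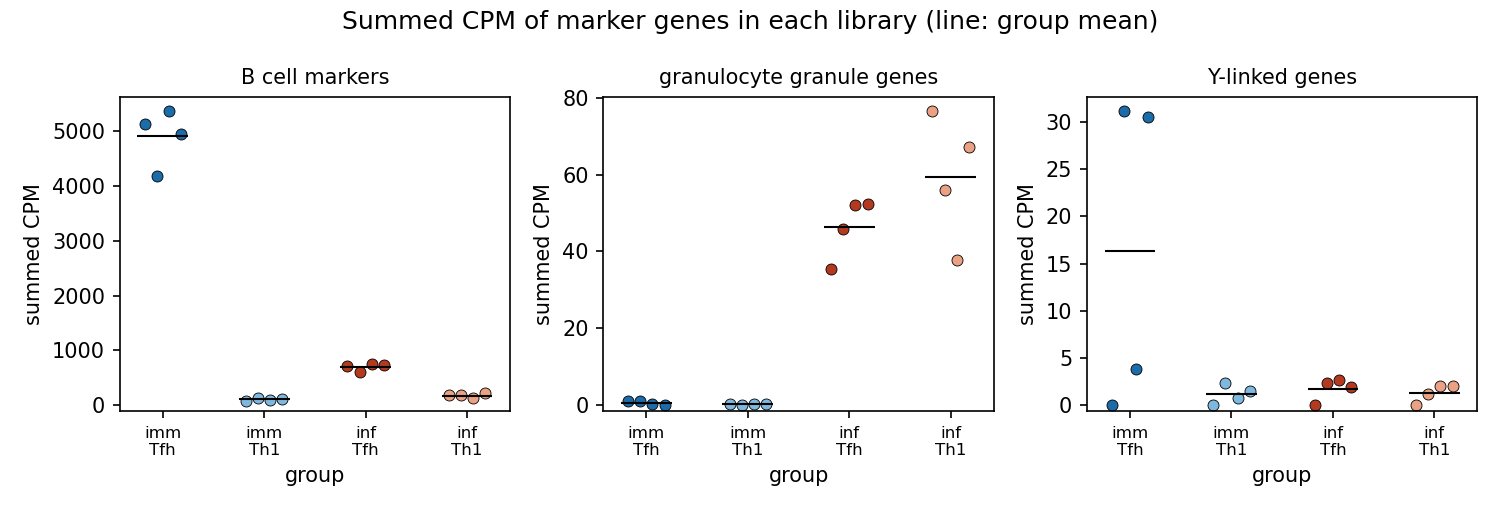
Summed CPM (y axis) of 18 B cell markers, 17 granulocyte granule genes and 4 Y-linked genes (panels) in each group (x axis; imm, immunization; inf, infection), 1 point per library with a line at the group mean. B cell markers average 4909 CPM in immunization Tfh, granule genes 46.4 and 59.4 CPM in infection Tfh and Th1, and Y-linked genes reach 31.1 and 30.5 CPM in 2 immunization Tfh libraries.

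The fourth comparison set immunization against infection within Th1 and gave the most calls of the 5 comparisons, 3710 genes higher and 3432 lower, with 3054 at least 2-fold. Id3, Tcf7 and Il6ra, a receptor chain for interleukin-6, were higher after immunization by 6.35 ± 0.11, 4.43 ± 0.09 and 4.65 ± 0.13 on the log2 scale: Tcf7 averaged 1269 ± 109 CPM in immunization Th1 and 59.0 ± 5.17 CPM in infection Th1. Gzmb fell from 1632 CPM after infection to 20.1 ± 5.54 CPM after immunization, Nkg7 from 1499 to 40.4 CPM and S100a6 from 1199 to 124 CPM.

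Of the 38 measured Th1 program genes, 35 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 2.17e-15; adjusted p = 0.0214 with an estimated correlation), and the member that rose, named after its value was seen, was Tnf. The Tfh program rose in 20 of 29 genes and fell in 4, also adjusted over the list alone (camera adjusted p = 8.73e-07; adjusted p = 0.0513 with an estimated correlation). The members that fell, named after their values were seen, were Pdcd1, Icos, Il21 and Batf. Naive and memory precursor genes rose in 15 of 20 cases and fell in 2, also adjusted over the list alone, among them Id3 and Tcf7 (camera adjusted p = 3.83e-07; adjusted p = 0.0549 with an estimated correlation). Cd27 and Txk fell, and were named after their values were seen. Early T cell receptor response genes rose in 18 of 24 cases and fell in 3, also adjusted over the list alone, with Egr1 and Egr2 up by 1.99 and 2.48 and Tnfrsf9 at -2.09 (camera adjusted p = 0.00357; adjusted p = 0.276 with an estimated correlation). Nr4a2 and Dusp5, named after their values were seen, were the others that fell.

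All 42 cell cycle genes fell, also adjusted over the list alone, with a median of -2.56 and with Mcm6, Pcna and Cenpa at -1.71, -1.80 and -2.20 (camera adjusted p = 6.63e-16; adjusted p = 0.279 with an estimated correlation). Glycolysis genes fell in 17 of 20 cases and rose in 2, or 17 and 3 adjusted over the list alone, with Tpi1, Gapdh and Pfkp at -1.89, -1.41 and -1.38 (camera adjusted p = 7.62e-06; adjusted p = 0.126 with an estimated correlation). Pfkm and Aldoc rose, and were named after their values were seen. Cholesterol synthesis genes fell in 19 of 24 cases, also adjusted over the list alone, with Tmem97, Fdps and Fdft1 at -2.0, -1.24 and -0.99 (camera adjusted p = 0.000108; adjusted p = 0.170 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 39 of 41 cases, also adjusted over the list alone, with Cycs, Sdhb and Ndufb8 at -1.75, -0.98 and -1.05 (camera adjusted p = 4.84e-12; adjusted p = 0.139 with an estimated correlation). With the GC and length offsets 33 of the 41 fell and 2 rose, the median went from -0.72 to -0.30, and Sdhb went to -0.60.

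Il17rb, Adh1, Hrh4 and Apol9a had no reads in infection Th1 and were at least 153-fold, 59.5-fold, 45.6-fold and 42.2-fold higher after immunization; Apol9a has a near-identical neighbour, so its count is uncertain. St8sia6 had 2 fragments in infection Th1, a ratio of 512 (141 to 4230), and Lrig1 rose by 8.32 ± 0.40 on the log2 scale. Ccl3 had no reads in immunization Th1 and was at least 614-fold lower there, followed by Ermn, Serpinb9b, S100a8 and Tppp3 at 146-fold, 141-fold, 98.6-fold and 84.3-fold lower at least, and Ccl4 averaged 0.239 against 147 CPM. Myeloid and dendritic markers fell in 18 of 19 cases, also adjusted over the list alone, with Cst3, Lyz2 and Itgam at -1.48, -3.52 and -5.94 (camera adjusted p = 5.29e-08; adjusted p = 0.0245 with an estimated correlation). The summed granulocyte granule genes were at 0.282 ± 0.200 CPM in immunization Th1 and 59.4 ± 16.6 CPM in infection Th1.

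The 2 stimulus comparisons share no libraries. In both cell types 1878 genes were higher and 1901 lower after immunization, against 883 and 817 for independent lists, and 368 were called in opposite directions. Across genes the log2 fold changes had r = 0.646 and rho = 0.630.

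**Figure D4:**
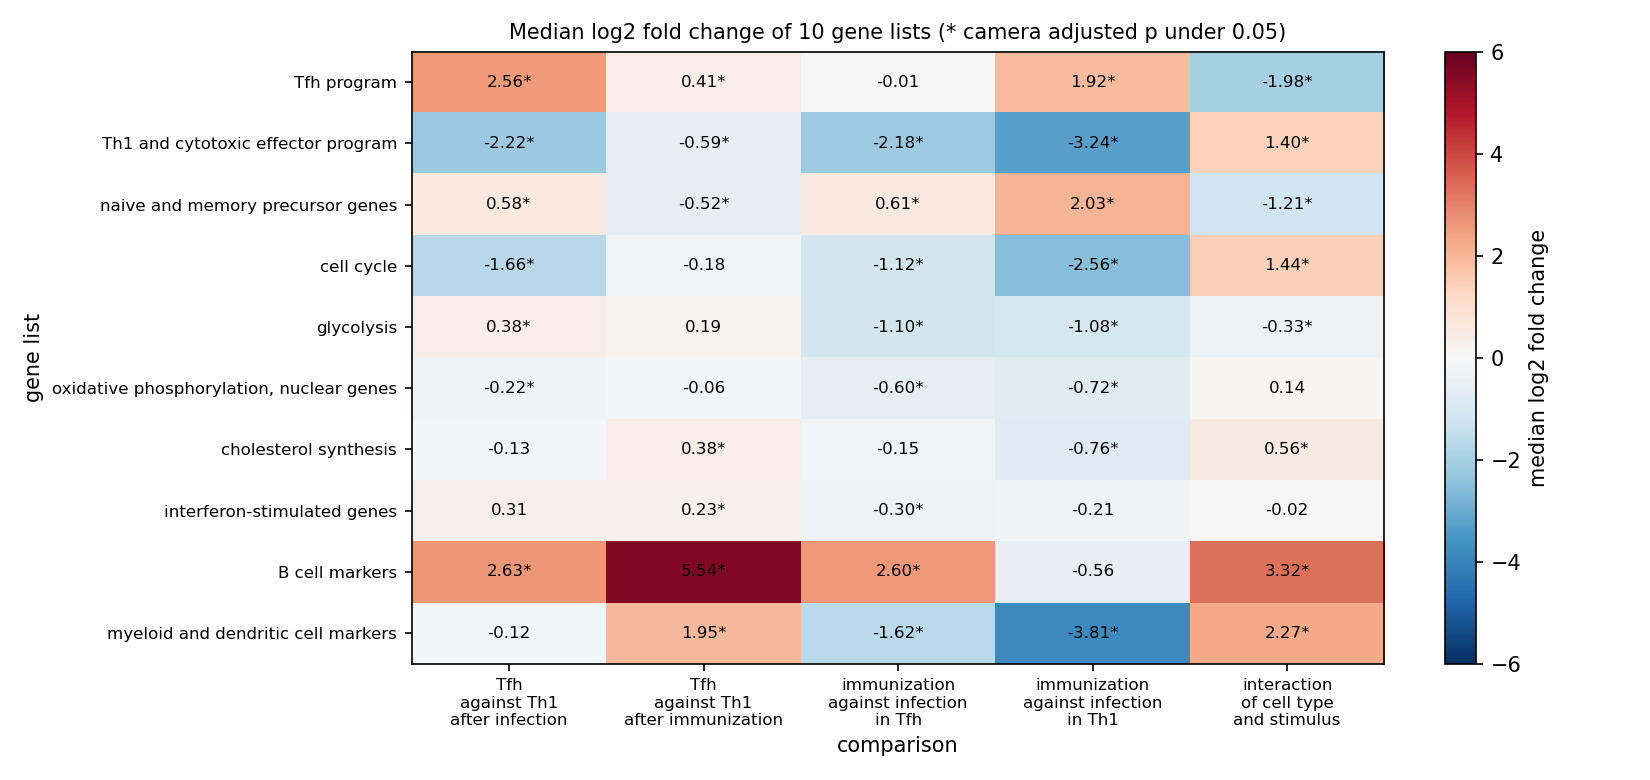
Median log2 fold change of 10 gene lists (y axis) in the 5 comparisons (x axis), with the value in each cell, red above 0 and blue below, and a star where the camera adjusted p was under 0.05. The Tfh program has a median of 2.56 for Tfh against Th1 after infection and 0.41 after immunization, and the Th1 program is lower after immunization in both cell types.

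The last comparison tested whether the Tfh-Th1 difference itself differed between the stimuli, as the difference after immunization minus that after infection. It did for 3759 genes, and for 3144 of them the Tfh-Th1 difference was larger in size after infection. Of the 3759, 2660 were called after infection alone, 337 after immunization alone, 317 after both with the same sign and 307 after both with opposite signs. Tcf7 and Id3 were far lower in Th1 than in Tfh after infection, but averaged 1269 and 455 CPM in immunization Th1 beside 1315 and 373 CPM in immunization Tfh (interaction -4.53 ± 0.11 and -5.66 ± 0.14). Ccr7 was higher in Tfh after infection and higher in Th1 after immunization (interaction -6.10 ± 0.26, adjusted p = 1.31e-12), and Nsg2 averaged 196, 176 and 179 CPM in immunization Tfh, immunization Th1 and infection Tfh but 2.20 CPM in infection Th1.

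The Tfh program had a lower interaction in 22 of 29 genes and a higher one in 3, or 23 and 3 adjusted over the list alone (camera adjusted p = 9.02e-15; adjusted p = 0.0139 with an estimated correlation), with Tnfsf8, a ligand of the TNF family, at -4.53. The 3 with a higher interaction, named after their values were seen, were Il21, Maf and Cd40lg. The Th1 program had a higher interaction in 28 of 38 genes and a lower one in 1, also adjusted over the list alone (camera adjusted p = 9.83e-12; adjusted p = 0.0306 with an estimated correlation), with Cxcr6, Gzmb and Cx3cr1 at 3.69, 3.64 and 7.95. Tnf, named after its value was seen, was the member with a lower interaction. Naive and memory precursor genes had a lower interaction in 14 of 20 cases, or 16 adjusted over the list alone, led by Id3, Tcf7 and Ccr7 (camera adjusted p = 2.40e-09; adjusted p = 0.0306 with an estimated correlation). Transcription regulators had a lower interaction in 34 of 62 cases and a higher one in 12, or 35 and 14 adjusted over the list alone (camera adjusted p = 6.00e-04; adjusted p = 0.0488 with an estimated correlation). Among these Irf8 averaged 126 and 22.9 CPM in immunization Tfh and Th1 and 97.8 and 123 CPM in infection Tfh and Th1. The summed B cell markers were also higher in immunization Tfh than Th1, at 4909 against 108 CPM. Whether the Irf8 reads there came from the T cells was not tested. All 42 cell cycle genes had a higher interaction, also adjusted over the list alone, with Cdt1, Mcm4 and Pcna at 1.57, 1.16 and 1.12 (camera adjusted p = 9.02e-15; adjusted p = 0.301 with an estimated correlation).

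B cell markers had a higher interaction in 16 of 18 cases, also adjusted over the list alone, with H2-Ab1, Cd74 and H2-Eb1 at 4.16, 3.66 and 3.94 (camera adjusted p = 2.45e-12; adjusted p = 0.0144 with an estimated correlation). Myeloid and dendritic markers did so in 10 of 19 cases, or 13 adjusted over the list alone (camera adjusted p = 2.01e-05, and adjusted p = 0.0549 with an estimated correlation). Cst3, Spi1 and Tyrobp were at 0.99, 3.80 and 2.98, and the list median of 2.27 was 2.10 with the members without reads at their bound. Here too, separate sources of these and the B cell markers were not tested. Of the remaining genes named by rule, Prr5 averaged 12.8 and 0.904 CPM in immunization Tfh and Th1 and 2.30 and 17.2 CPM in infection Tfh and Th1. Lrig1 averaged 17.7, 64.0, 5.24 and 0.178 CPM and Egr4, an early growth response gene, 2.51, 5.26, 1.16 and 0 CPM in the same order of groups. Dennd5b and Bcar3 reached 8.11 and 25 CPM in immunization Tfh and at most 0.241 and 2.55 CPM in the other groups, while Plagl1 reached 7.68 CPM in infection Tfh and at most 0.268 CPM elsewhere. Ccl3 was at 69.3 CPM in infection Th1 and Ica1l was without reads there. The interaction call of Plagl1 was lost without immunization Th1 replicate 2 (-4.28, adjusted p = 0.941).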

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

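Of the tests in this part, those of a common ratio over B cell markers or granule genes, of expression by the T cells themselves, of mixed sorts, of GC content and length, and of naive genes were chosen only after the results they bear on had been seen, and the others were planned.

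The Tfh-Th1 difference differed between the stimuli for 3759 genes by the interaction test. Among the label checks, the log2 interaction was -2.10 for Bcl6, -3.08 for Cxcr5, 0.91 for Il21, -1.90 for Il4, 1.23 for Tbx21, 1.36 for Ifng and 2.81 for Prdm1. Among the genes with the most extreme values it was 8.91 for Ccl3, 7.95 for Cx3cr1, 7.09 for Dennd5b, 6.81 for Bcar3 and 6.62 for Prr5, and -8.32 for Plagl1, -7.38 for Ica1l, -7.00 for Egr4, -6.58 for Lrig1, -6.17 for Nsg2 and -6.10 for Ccr7. Ccl3, Ica1l and Egr4 have a group without reads, and Dennd5b, Bcar3 and Plagl1 one with a single fragment, so the fitted values of these 6 genes depend on the prior count or on counting error and give a direction rather than a size. Cx3cr1 in immunization Th1 and Lrig1 in infection Th1 were also low, at 0 to 0.4 and 0 to 0.332 CPM per library, so their sizes are uncertain as well. The interaction call of Plagl1 was lost without immunization Th1 replicate 2 (-4.28, adjusted p = 0.941). The median log2 interaction was -1.98 for the Tfh program, 1.40 for the Th1 program, 1.44 for cell cycle, -0.33 for glycolysis, 0.56 for cholesterol synthesis, -1.21 for naive and memory precursor genes, -0.72 for early T cell receptor response genes, -0.54 for transcription regulators, 3.32 for B cell markers and 2.27 for myeloid markers (2.10 with members without reads at their bound). The cholesterol, early T cell receptor response and glycolysis lists had camera adjusted p of 8.26e-05, 0.00927 and 0.0497, and 0.169, 0.312 and 0.504 with an estimated correlation. With each of the 16 libraries left out in turn, the glycolysis call was lost in 11 cases (0.0520 to 0.0848), and kept without immunization Th1 replicate 2 or 3, infection Tfh replicate 4, or infection Th1 replicate 2 or 3.

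For each comparison other than the interaction, its 8 libraries were also split in the other ways possible. Every other split mixes libraries of both groups, which widens the spread within each set, so low counts there do not exclude chance. Chance differences between animals could not be tested, since the labels do not say that libraries came from separate animals. Only 1 of 35 splits, the real one, gave as many genes: 5259 for Tfh against Th1 after infection, 1655 after immunization, 4860 between stimuli in Tfh and 6809 in Th1, in fits of the 8 libraries, and the highest other split gave 0 each time. For the interaction, 1 of 100 splits within stimulus reached the real 3759. The highest other split gave 3506, and it and the next 4 (3387, 3246, 3235 and 3141) kept the infection libraries as labelled and mixed only the immunization libraries. These splits still hold the whole Tfh-Th1 difference after infection, so their counts do not tell how much the immunization libraries add.

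B cell markers were at 4909 CPM in immunization Tfh, with Cd74, H2-Ab1 and Cd79a at 1735, 558 and 216 CPM, although a sort of CD45.2+ donor T cells would remove recipient B cells. RNA of B cells in the Tfh sorts may account for this: the ratio of infection to immunization excess had an SD of 0.653 on the log2 scale over 18 markers, against a median of 1.96 in random sets from 270 genes, at percentile 0. The markers also moved together between Tfh libraries, with a mean correlation of 0.196 against 0.001 in matched sets (percentile 99.8). Expression by the Tfh cells themselves cannot be told apart from this, since all 18 markers were higher in Tfh than in Th1, which both explanations give. The markers' ratios ran from 0.0324 to 0.313, with a median of 0.123, and 139 of the 372 genes at least 2-fold higher in immunization Tfh than Th1, the markers among them, lay within that range.

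Granulocyte granule genes were seen almost only in the infection libraries, at 46.4 CPM in Tfh and 59.4 CPM in Th1 against 0.565 and 0.282 CPM after immunization, with S100a9, S100a8 and Chil3 at 13.2, 11.1 and 8.38 CPM in infection Th1. RNA of spleen granulocytes, which a sort of T cells would remove, is a candidate source: the log2 ratio of infection Tfh to Th1 had an SD of 0.476 over 11 measured granule genes, against 1.28 in random sets (percentile 0.41). S100a8, S100a9, Mpo and Csf3r of this list are also in the myeloid list. Expression by the T cells cannot be told apart from it, since all 11 genes were lower after immunization in both cell types, which either source would give. Infection and spleen changed together, so neither can be named as the origin.

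For 681 genes at least 2-fold higher in infection Tfh than Th1 and with a negative interaction call, the median ratio of immunization Th1 to immunization Tfh was 0.982 (quartiles 0.818 and 1.18). These genes were picked by their negative interaction, which itself favours ratios near 1. Mixed-in cells with the Cxcr5 level of the Tfh sort would bring Cxcr5 at the same ratio, but that ratio was 0.109, and 0.132 in the highest library. The values argue against mixing of such cells as the cause. Since the sort markers are not given, Tfh-like cells with low Cxcr5 in the Th1 sort are not excluded. GC and length offsets left the interaction call in 97.02% (651) of the 671 genes with a GC value. Of all 3759 interaction calls, 3386 were kept with these offsets. The 681 genes were picked for a large difference and a call, which itself favours keeping the call. Nearly all of their calls thus stood with the offsets, but the share cannot tell whether a smaller bias was present. A candidate explanation is a less differentiated state of immunization Th1 cells. The 12 naive genes outside the 681 and outside the Tfh program had a median immunization-infection difference of 1.45 in Th1. Of these, 10 were above 0 (exact two-sided sign test p = 0.0386, genes not being independent). The rise of the whole list in this comparison was known before, so the sign test adds no independent support. The whole naive list rose in Th1 in 15 of 20 genes and fell in 2, with a median of 2.03. In Tfh it also rose, in 13 genes with 2 falling and a median of 0.61, so the direction was not particular to Th1. A less differentiated state stays a hypothesis, and stimulus and organ remain open as untested differences.

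Single libraries stood apart from the other 3 of their group in 21 of 417 groups of values, where chance gives about 1 in 20, by the gap to the nearest other library against the range of the group. In CPM these were Bcl6 in immunization Th1 replicate 1 (30.2), Cxcr5 in infection Tfh replicate 3 (645), Il4 in infection Tfh replicate 3 (4.51), Ica1l in immunization Tfh replicate 3 (10.4), Wnt10a in immunization Th1 replicate 2 (2.68) and infection Tfh replicate 1 (13.5), Padi4 in immunization Th1 replicate 1 (2.00) and Havcr2 in immunization Th1 replicate 1 (0.200). Cdt1 in infection Tfh replicate 3 (45.2), Tox2 in immunization Th1 replicate 4 (37.5), Fdps in immunization Th1 replicate 4 (28.8), Srebf2 in immunization Tfh replicate 1 (283), Mt3 in infection Th1 replicate 3 (14.3) and S100a8 in infection Tfh replicate 4 (10.3) were others. The rest were Usp18 in infection Tfh replicate 1 (154), Top2a in immunization Tfh replicate 1 (101) and infection Tfh replicate 3 (359), Egr1 in infection Th1 replicate 4 (91.0), Cst3 in immunization Tfh replicate 2 (48.9), H2-Eb1 in infection Th1 replicate 3 (15.9), and the total count of immunization Tfh replicate 2 (5045662, against 7035426 to 7348026 in the others).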

How the results depend on the processing

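Leaving out Rn45s, the genes at the B cell marker ratio or 2 immunization Tfh libraries, and the GC and length offsets, were tests chosen only after the results were seen, and the other alternatives were planned. No called result changed direction under any alternative run, while medians near 0 of some lists without a call changed sign. With a log2 fold change of at least 1 required, the counts were 1986 and 609 for Tfh against Th1 after infection and after immunization, 1492 and 3054 for the stimuli in Tfh and Th1, and 1684 for the interaction, as a stricter criterion must lower them. Without the 2 immunization Tfh libraries with the most Y-linked reads, Tfh against Th1 after immunization gave 898 genes, 850 of them among the 1746. Leaving out other pairs of that group gave 877 to 1532, so the drop is not particular to this pair. Apart from the stricter criterion, leaving out the 2 libraries with the most Y-linked reads also gave the lowest counts for the stimuli in Tfh, 4083, and for the interaction, 3323. Other pairs were not left out for these comparisons, so the lower counts cannot be told apart from the effect of having fewer libraries. Of the 105 list comparisons, 47 were called by camera, 17 with an estimated correlation and 81 by fry, which does not compare a list with other genes.

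Under the other alternatives the counts ranged, in the order above, from 5125 to 5816, 1555 to 2336, 4380 to 5207, 6547 to 7350 and 3557 to 4287. With 1 library left out they ranged from 4964 to 5440, 1363 to 1769, 4771 to 5031, 6767 to 6989 and 3422 to 3999, and called lists from 44 to 52. The genes shared by the Tfh-Th1 comparisons, 824 with all libraries, ranged from 789 to 812 under RLE size factors, the stricter filter and the replicate block, the only 3 alternatives run on shared genes, and from 663 to 866 with 1 library left out, and those shared by the stimulus comparisons, 3779, from 3559 to 3787 and from 3405 to 3764. Results of single named genes kept their side of the threshold in 1716 cases under these 3 alternatives, DESeq2 and the GC and length offsets, gained a call in 5 and lost one in 4, and with a library left out in 3279, 7 and 26 cases. With GC and length offsets 3676 of the 5170 genes called between stimuli in Tfh were kept, and the cause was not tested.

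Some replicate structure is shared: as deviations from the group means, same-numbered Tfh and Th1 libraries had r of 0.523, 0.077, 0.443 and 0.367 after infection and 0.252, 0.096, 0.009 and 0.273 after immunization. The fourth principal component, with 2.96% of the variance, also ordered Tfh and Th1 libraries alike by number within each stimulus, and replicate 1 of every group had 0 Y-linked reads. In contrast, the Y-linked reads of replicates 2 and 4 after immunization summed to 31.1 and 30.5 CPM in Tfh but 2.36 and 1.56 CPM in Th1. Not every library correlated best with its own number and the labels do not say what a number shares, so the numbers were not taken to pair the libraries, but a common origin within a stimulus is not excluded. Across the stimuli, same-numbered libraries had r of -0.4, -0.038, -0.1 and -0.282 in Tfh and -0.168, -0.113, -0.058 and -0.333 in Th1. A replicate block with 1 effect per number over both stimuli therefore does not model structure shared within a stimulus only. It gave 5412, 1691, 5075, 7060 and 3689 genes and 47 lists, 46 of them among the 47 called without it. With it, camera did not call the glycolysis interaction (adjusted p = 0.0708). It called interferon-stimulated genes for Tfh against Th1 after infection (adjusted p = 0.0433). A block within stimulus gave 5816, 2336 and 4287 genes for the Tfh-Th1 comparisons and the interaction, against 5491, 1746 and 3759 without a block. Depth limits genes near the floor of 3 fragments over a group, where only bounds or counting intervals are given.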

Other observations

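The lists in this part were fixed with the others, and of the tests only the GC and length offsets were chosen after the results were seen. The regulatory T cell program fell in 8 of 17 genes and rose in 3 in immunization Tfh against Th1, also adjusted over the list alone (camera adjusted p = 0.0228; adjusted p = 0.122 with an estimated correlation). The inhibitory receptor gene Tigit averaged 143 and 15.9 CPM in immunization Tfh and Th1, Nrp1 223 and 363 CPM and Capg 89.1 and 216 CPM. In infection Tfh and Th1 Tigit stood at 302 and 289 CPM, and its interaction was 3.10 ± 0.19 (adjusted p = 2.77e-10, edgeR). Early T cell receptor response genes fell in 7 of 24 cases and rose in 2 in immunization Tfh, or 11 and 2 adjusted over the list alone, with Irf4, Ier2 and Dusp2 at -0.96, -0.63 and -0.82 (camera adjusted p = 0.0159; adjusted p = 0.339 with an estimated correlation). Of 3 measured CD8 T and NK cell markers, 2 rose there, or 3 adjusted over the list alone (camera adjusted p = 0.00462; adjusted p = 0.0488 with an estimated correlation), with Klrb1c at 16.6 and 3.85 CPM.

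Adhesion and migration receptors fell in 18 of 33 cases and rose in 8 in infection Tfh against Th1, also adjusted over the list alone (camera adjusted p = 0.0491; adjusted p = 0.377 with an estimated correlation). The call was lost without infection Tfh replicate 3 (0.0768) and without infection Th1 replicates 1, 2 and 4 (0.0684, 0.0520 and 0.0560). After immunization 17 fell and 7 rose, or 17 and 8 adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.279 with an estimated correlation), and Gpr183, an oxysterol receptor that positions lymphocytes, averaged 328 CPM in Tfh and 182 CPM in Th1, beside 61.8 and 56.0 CPM after infection.

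The Th2 and Th17 programs, coinhibitory receptors, dissociation and heat shock genes, cytokines and their receptors, and stromal markers were not called by camera in any of the 5 comparisons with all libraries. Their lowest camera adjusted p were 0.0531 for Th2 genes, 0.0531 for cytokines, 0.0715 for heat shock genes and 0.129 for coinhibitory receptors, all between the stimuli in Tfh, 0.0987 for Th17 genes after immunization and 0.191 for stromal markers in the interaction. With 1 library left out, calls between the stimuli in Tfh appeared for Th2 genes without immunization Tfh replicate 4 (0.0499) or infection Tfh replicates 2, 3 or 4 (0.0485, 0.0335 and 0.0355), for cytokines without immunization Tfh replicate 1 (0.0475) or infection Tfh replicates 2 or 4 (0.0380 and 0.0351), for heat shock genes without immunization Tfh replicate 1 (0.0475) and for Th17 genes without infection Tfh replicate 4 (0.0477). Members moved in both directions: in Tfh, Il1rl1 and Gata3 of the Th2 list averaged 0.443 and 166 CPM after immunization and 48.1 and 56.7 CPM after infection. Likewise Il12rb2 and Ifngr2 of the cytokine list averaged 4.51 and 31 CPM after immunization and 44.6 and 2.40 CPM after infection, and Nt5e of the coinhibitory list 133 CPM in infection Tfh and 4.37 CPM in infection Th1. After infection the Th2 list had a median of 0.98, or 0.47 with the member without reads at its bound, with a camera direction down, and the Th17 list a median of -0.78 and a mean of 0.18. Medians near 0, all of lists that camera did not call in the comparison, changed sign with the scaling for heat shock genes in both Tfh-Th1 comparisons, for interferon-stimulated and regulatory T cell genes in the interaction, and for the Tfh program and transcription regulators between stimuli in Tfh. The median of adhesion receptors between stimuli in Tfh went from 0.14 to -0.03 with the GC and length offsets.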
